A study of Mus musculus with 4 samples.

How the data were processed

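Poly(A) RNA of mouse bone marrow-derived macrophages was sequenced in 4 libraries, 2 from cultures given Adcy7-targeted and 2 from cultures given Rosa-targeted CRISPR-Cas9 lentivirus. Per the labels' protocols, RNA with an integrity number above 7 was bound to oligo(dT) beads, fragmented and reverse transcribed, and the libraries had inserts of about 300 bp with a spread of 50 bp. The labels do not name a method that keeps strand, so reads from overlapping or antisense genes may not be told apart.

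The deposited table held estimated counts (expected counts) per Ensembl gene, already rounded to whole numbers and not normalized by the authors as far as the values show. Per the submitters' processing notes, fastp, HISAT2, StringTie and edgeR were used with the mouse build GRCm39. Their versions, order and settings, the annotation release and the step from StringTie to counts are not given in the sources used here. Low counts piled up at multiples of 4. Among genes with 1 to 40 counts, 30.54% to 32.17% per library were multiples of 4, where 25% would be if there were no step. This would follow if 1 sequenced fragment were worth about 4 counts, and the library totals of 61782358 to 71914179 counts would then stand for about 4 times fewer fragments. Most low counts were not multiples of 4, so this is an assumption, and the fragment counts, floors and bounds rest on it. The counts were tested as deposited, and counts divided by 4 were an alternative chosen after seeing the data.

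Gene names, types, chromosomes and neighbours came from an annotation of another build, GRCm38, for which 55141 of 55401 IDs had a symbol. No coordinates are given, since the builds differ. Where several IDs shared a symbol (106 symbols), the ID with the most counts kept it. Of the 55401 genes, 32305 had no count in any library.

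Groups were taken from the treatment label. The column names of both knockout libraries hold KO3 and the replicate number. They were matched to the sample titles by KO and that number, and what the digit in KO3 stands for is not given. Genes were filtered with filterByExpr, which left 15832, scaled with TMM and tested with edgeR 4.0.16 (quasi-likelihood test, 2 residual degrees of freedom, Benjamini-Hochberg adjustment over all tested genes, threshold 0.05) in R 4.3.3. Levels are CPM of the deposited totals. The common dispersion was 0.0238. Before the data were examined, 24 pathway lists and 14 cell type lists were fixed. Each list with at least 5 tested genes was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and also with camera's estimated correlation and with fry. Adjustment was over the lists of each kind. Of the pathway lists 10 passed camera with the preset correlation, none with an estimated correlation (0 adjusted, 2 at an unadjusted p under 0.05), and 17 passed fry, which asks only whether a list's genes moved on balance in 1 direction. Of the cell type lists 9 passed camera, none with an estimated correlation (0 adjusted and 0 unadjusted), and 11 passed fry. With 2 libraries a group the estimated correlations rest on few values. Camera with an estimated correlation also rests on the 2 residual degrees of freedom, so passing after adjustment was hard at any correlation. The cytokine list had an estimated correlation of -0.01, below the preset value, yet its unadjusted camera p went from 7.46e-10 to 0.0201. Not passing that test therefore says little about a list.

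The named genes follow a rule fixed before the data were examined. It took the tested adenylyl cyclases and Gt(ROSA)26Sor, the 12 largest rises and the 12 largest falls among genes that passed with a mean of at least 1 CPM and separated groups, up to 4 members with the smallest adjusted p from each list, and 2 members from a list without any. Of the genes this rule took, 3 are not reported here. A fold against a group with no count is a lower bound, set against a floor of 3 fragments (12 counts) over the pooled libraries of the group, which is 0.0898 CPM in the knockout and 0.0885 CPM in the control. With 1 to 3 fragments the ratio has a 95% exact binomial interval. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Genes with near-identical copies are uncertain, because reads can be split among the copies. Examples are Gapdh, Rpl7a and Rpl17, whose replicates differed widely.

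The gene test was checked on simulated counts drawn from the means and library sizes of the 4 libraries, with 200 genes changed, of which 66 for each fold were among the 15398 tested. It recovered 27.3% of genes changed 1.5-fold, 51.5% of those changed 2-fold and 80.3% of those changed 4-fold. Far fewer genes were changed in the simulation than the 7848 that passed in the data, which made the adjusted threshold stricter. These shares and the share of false calls given next therefore need not hold for the data. Of the unchanged genes 4.89% had an unadjusted p under 0.05. Of 124 genes called, 19 (15.32%) were unchanged genes, above the nominal 5% share. A limit of 15% on that share, set beforehand for the check, was missed by this draw, and the check was then based on the unadjusted p-values, with the test itself left as it was. After that miss, other random draws and other settings of the quasi-likelihood test were tried on simulated counts outside the rerun scripts; none of them was adopted, and the first draw is the one reported. A raised list was called and 0 of 20 unchanged lists were. The simulated genes varied independently and all genes of the raised list were raised. This check could therefore not show false calls that come from correlated genes. In the data, the pathway lists that passed had estimated correlations of up to 0.507 (NRF2 and oxidative stress).

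Alternatives were RLE and upper-quartile factors, no low-count filter, a filter of CPM above 1 in 2 libraries, DESeq2 1.42.0, limma-voom, edgeR with legacy and robust options, leaving out mitochondrial genes and genes with over 1% of a library, the replicate number as a block, a threshold of 0.01, the other list tests, and leaving out each library in turn.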

Results

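RNA-seq measured poly(A) RNA in bone marrow-derived macrophages (BMDM), which are macrophages grown in culture from marrow cells, here of C57BL/6J mice. The marrow cells had received lentivirus carrying CRISPR-Cas9 at a multiplicity of infection of 30 on day 1 after isolation, and became macrophages over 5 days. In 2 libraries the virus targeted Adcy7 (Adcy7 knockout), the gene of an adenylyl cyclase, an enzyme that makes the messenger cyclic AMP. In the other 2 libraries it targeted Rosa (Rosa control), a locus widely used as a neutral target site. All 4 libraries carried batch number 1. The deposited table gave estimated read counts for 55401 Ensembl genes. Knockout replicates 1 and 2 held 71914179 and 61782358 counts, and control replicates 1 and 2 held 65766496 and 69874955. Genes with at least 1 count numbered 19697 and 19565 in the knockout libraries and 18641 and 18659 in the control libraries. Across genes, the Pearson correlation of log2 CPM (each count scaled to the library total) was 0.9809 between the knockout libraries, 0.9815 between the control libraries, and 0.9085 to 0.9141 between groups, with genes not being independent replicates. Libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom, on counts divided by 4, of 10.64 in the knockout and 6.24 in the control, which speaks only against both being copies of 1 library. The labels do not say whether replicates came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

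Adcy7 mRNA was lower in both knockout libraries but still present. Adcy7 (ENSMUSG00000031659, a protein-coding gene on chromosome 8) was at 59.1 CPM ± 0.413 (SD, n = 2) in the knockout and 123 CPM ± 1.95 (SD, n = 2) in the control. This was a log2 fold change of -1.05 with a standard error (SE) of 0.09, or 48.4% of the control level, at an adjusted p of 4.6e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The mRNA level does not measure how many gene copies were edited, since a small insertion or deletion can leave the mRNA in place. Of the 6 adenylyl cyclase genes tested, 2 rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone. Adcy6 rose from 0.427 CPM ± 0.0234 to 3.3 CPM ± 0.121 (SD, n = 2 each). Adcy8 had no count in the control and was at least 2.37-fold higher in the knockout, at a level of 0.213 CPM that lay near the floor. It lost its call without the low-count filter, without control replicate 1 and without control replicate 2. Adcy9, Adcy3 and Adcy2 had log2 fold changes of -0.06 (SE 0.23), -1.01 (SE 0.52) and 0.03 (SE 0.33). The transcript of the control locus, Gt(ROSA)26Sor on chromosome 6, was at 3.63 CPM in the knockout and 3.92 CPM in the control, a log2 fold change of -0.10 (SE 0.23) that did not pass.

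The comparison of Adcy7 knockout with Rosa control asks how the macrophage transcriptome differs once Adcy7 is targeted. Of 28 genes of inflammatory cytokines and chemokines, 23 were higher in the knockout libraries, among them Cxcl3, Cxcl1 and Nos2, by 136-fold, 91.9-fold and 26.4-fold. Of 29 macrophage identity genes 24 were lower, including the C1q complement chains, Apoe and Aif1. Of genes of cell division, cholesterol synthesis and ribosomal proteins, 42 of 43, 20 of 25 and 43 of 48 were lower, while 20 of 31 genes of glycolysis and hypoxia and 14 of 24 of the oxidative stress response were higher. Of markers of eosinophils, mast cells and basophils, and platelets, 8 of 9, 8 of 10 and 12 of 12 were higher. None of these lists passed camera with an estimated correlation, which was hard to pass with 2 residual degrees of freedom. Its adjusted p values were 0.378 for cytokines and for macrophage identity. They were 0.471, 0.378, 0.687, 0.687 and 0.845 for the 5 lists named next in that order, and 0.217 for each of the 3 marker lists. Of 15832 genes tested, 7848 (49.6%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3952 higher and 3896 lower. At least a 2-fold change was seen in 3508 of them, 1875 higher and 1633 lower. Both knockout libraries lay on the same side of both control libraries for 75.2% of all tested genes, where chance gives 33.3%. The labels do not give the number of guides, virus preparations or cultures behind each group, so differences between these go with the target.

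**Figure D1:**
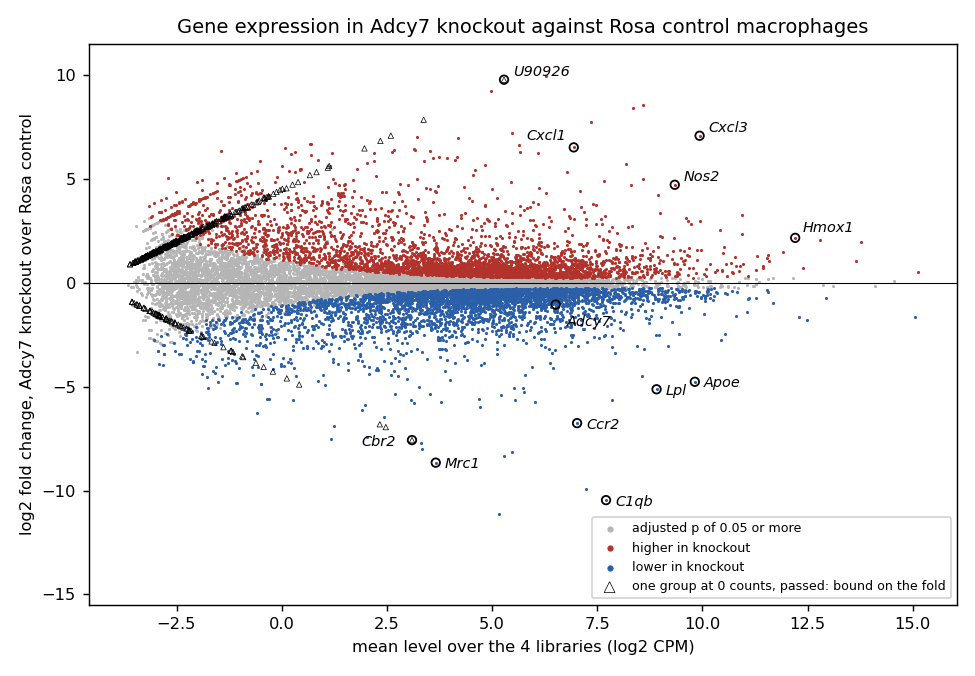
Log2 fold change (Adcy7 knockout over Rosa control, 2 libraries each) of the 15832 tested genes against their mean level in log2 CPM, with higher genes in red, lower genes in blue, and triangles at the bound of the fold for genes that passed with no count in 1 group. Adcy7 lies at -1.05, within the spread of the many lower genes.

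The genes with the largest rises had no count in the control, so their folds are lower bounds against a floor of 12 pooled counts. The RNA U90926 was at 77.9 CPM ± 2.17 (SD, n = 2) in the knockout, at least 879-fold higher. Slc1a2, a glutamate transporter gene, was at least 231-fold higher, Kcnf1, a potassium channel subunit gene, at least 136-fold, and Mir155hg, the host gene of miR-155, at least 114-fold. Ptx3, the gene of the secreted pattern recognition protein pentraxin, was at least 88.9-fold higher. Efcab6, Il17a, Rnf182, Ido2, Tet1, Pappa2 and Ighg1 were at least 49.4-fold, 46.8-fold, 40.3-fold, 36.4-fold, 28.9-fold, 26.5-fold and 23.5-fold higher. Relative to the mean, the libraries of Il17a and Ighg1 differed most among these, with means of 4.27 CPM ± 2.58 and 2.16 CPM ± 1.59 (SD, n = 2). Among the largest falls, Cbr2, Slc13a3, Kcnip3 and Galnt9 had no count in the knockout and were at least 190-fold, 123-fold, 112-fold and 24.2-fold lower. Cbr2 was at 17.1 CPM ± 2.21 (SD, n = 2) in the control. Mrc1, the mannose receptor, Cd5l and Rnase2a kept between 1 and 3 fragments in the knockout. Their control levels were 420-fold (95% counting interval 116 to 3473), 219-fold (74.7 to 1065) and 335-fold (92.4 to 2773) those of the knockout. Fcrls fell by 8.35 on the log2 scale (SE 0.22).

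Inflammatory cytokine and chemokine genes were the pathway list with the largest median change. Of 28 tested, 23 rose, 4 fell and 1 did not pass, with the same counts adjusted over the list alone, and the median log2 fold change was 4.25. The neutrophil-attracting chemokine genes Cxcl3, Cxcl1 and Cxcl2 rose from 14.4 CPM ± 3.05, 2.68 CPM ± 0.553 and 49.8 CPM ± 3.99 to 1940 CPM ± 53.7, 243 CPM ± 11.6 and 930.4 CPM ± 55.5 (SD, n = 2 each). Nos2, the inducible nitric oxide synthase, rose from 47.9 CPM ± 0.19 to 1250.1 CPM ± 67.2 (SD, n = 2 each). The list passed camera with a preset correlation (adjusted p = 5.97e-09), and had an adjusted p = 0.378 with an estimated correlation. Il18, which codes for a cytokine matured by the inflammasome, was among the members that fell, by 1.91 on the log2 scale (SE 0.19). Of 25 genes of the NF-kB pathway and its feedback, 19 rose, 3 fell and 3 did not pass, with the same counts adjusted over the list alone. Traf1, Nfkb2, Tnfaip3 and Sod2 rose 6.96-fold, 2.87-fold, 2.88-fold and 2.98-fold. The camera adjusted p of this list was 0.000175 with the preset correlation, and the adjusted p = 0.378 with an estimated correlation. Among 18 inflammasome and pyroptosis genes 5 rose and 7 fell, with the same counts adjusted over the list alone. Nlrp3, the sensor of the inflammasome, and Il1b rose 2.82-fold and 2.91-fold, while Pycard, its adaptor, fell by 0.96 on the log2 scale (SE 0.09). In the same knockout libraries, 12 of 12 platelet markers and 8 of 9 eosinophil markers were higher.

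Interferon-stimulated genes moved in both directions. Of 49 tested, 13 rose, 21 fell and 15 did not pass, or 13 and 23 adjusted over the list alone, with a median of -0.24. Gbp2 and Gbp3, which code for guanylate-binding proteins, rose 6.37-fold and 6.77-fold. Ifi213 and Phf11b fell by 3.18 (SE 0.19) and 2.25 (SE 0.15) on the log2 scale. All 14 genes of MHC class II presentation passed, 9 higher and 5 lower, with the same counts adjusted over the list alone. H2-Aa, H2-Ab1 and Cd74 rose 2.4-fold, 2.14-fold and 2.01-fold, and H2-DMa fell by 1.75 on the log2 scale (SE 0.15). B cells and dendritic cells also carry class II molecules, and 9 of 12 B cell and 8 of 17 dendritic cell markers were higher in the same libraries. Neither list passed camera (adjusted p of 0.271 and 0.276 with the preset correlation), and the second passed fry (adjusted p of 0.364 and 0.029).

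Macrophage identity genes were lower in the knockout. Of 29 tested, 24 fell, 3 rose and 2 did not pass, with the same counts adjusted over the list alone, and the median log2 fold change was -1.69. The genes of the C1q chains, which start the classical complement pathway, were close to absent. C1qb and C1qc were at 418 CPM ± 48.7 and 301 CPM ± 32.8 in the control and at 0.276 CPM ± 0.298 and 0.314 CPM ± 0.129 in the knockout (SD, n = 2 each). C1qa was at 71.7 CPM ± 6.79 in the control and kept 1 fragment in the knockout, a ratio of 2392 (95% counting interval 429 to 94525). Aif1 fell by 8.12 on the log2 scale (SE 0.19). Apoe, a lipoprotein component that macrophages secrete, fell from 1743 CPM ± 149 to 63.4 CPM ± 4.02 (SD, n = 2 each). The 3 members that rose were Gpnmb, Cd14 and Lgals3, named after their values were seen. The camera adjusted p was 5.2e-08 with the preset correlation, and the adjusted p = 0.378 with an estimated correlation. Of 22 complement and Fc receptor genes, 15 fell, 6 rose and 1 did not pass, with the same counts adjusted over the list alone. C3ar1, a receptor for a complement fragment, was at 621 CPM in the control and 74.7 CPM in the knockout. This list had a camera adjusted p of 0.0133, and an adjusted p = 0.436 with an estimated correlation. Classical monocyte markers were also lower, with 7 of 11 falling and 2 rising, or 8 and 3 adjusted over the list alone. Ccr2, the chemokine receptor that guides monocytes to tissue, went from 257 CPM ± 12 to 2.38 CPM ± 0.508 (SD, n = 2 each). S100a4, F13a1 and Sirpb1c fell by 2.67, 2.53 and 2.38 on the log2 scale. The monocyte list had a camera adjusted p of 0.0241, and an adjusted p = 0.241 with an estimated correlation. In the same knockout libraries 8 of 9 eosinophil, 8 of 10 mast cell and basophil and 12 of 12 platelet markers were higher.

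**Figure D2:**
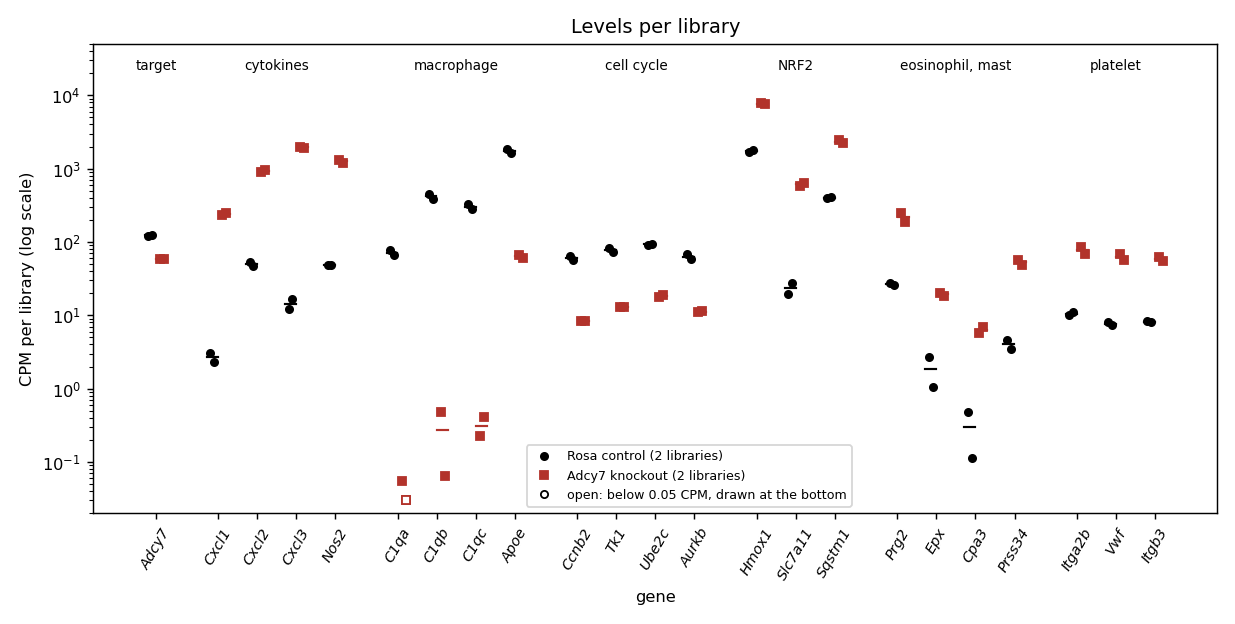
CPM per library on a log scale for genes named in the text, with black circles for the 2 Rosa control libraries, red squares for the 2 Adcy7 knockout libraries, and short lines at group means of at least 0.05 CPM. Adcy7 stood at 59.1 CPM in the knockout against 123 CPM in the control, and Cxcl3 at 1940 CPM against 14.4 CPM.

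Alternative activation genes moved in both directions. Of 24 tested, 8 rose and 9 fell, or 9 and 9 adjusted over the list alone, with a median of 0.05, a mean of -0.91, a camera adjusted p of 0.79 and a fry adjusted p of 0.0354. Il10, the gene of an anti-inflammatory cytokine, and the lipoxygenase gene Alox15, which is also on the eosinophil list, of which 8 of 9 members rose, were 36-fold and 32.3-fold higher. Arg1, the gene of arginase, fell from 2418 CPM ± 182 to 357 CPM ± 6.12 (SD, n = 2 each). Of 26 genes of LXR targets and lipid handling, 7 rose and 12 fell, with the same counts adjusted over the list alone, at a camera adjusted p of 0.144 and a fry adjusted p of 0.00844. Lpl, the lipoprotein lipase gene, fell by 5.12 (SE 0.11) and Pltp fell by 4.43 (SE 0.16) on the log2 scale, while Hilpda, which codes for a lipid droplet protein, rose 12.7-fold. Of 39 phagocytosis and lysosome genes, 17 rose and 13 fell, or 17 and 14 adjusted over the list alone, with a median of -0.03 and a mean of 0.07. Gla, a lysosomal galactosidase gene, rose 2.65-fold, and Stab1 and Gas6, which take part in the clearance of dead cells, fell by 2.57 and 3.57 on the log2 scale. Of 39 genes of adhesion, migration and matrix remodelling, 19 rose and 15 fell, or 19 and 16 adjusted over the list alone. The collagenase gene Mmp13 rose 23.7-fold, and the chemokine receptor gene Cx3cr1 had a log2 fold change of -4.08 (SE 0.13).

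Cell division genes were lower in the knockout. Of 43 cell cycle and proliferation genes, 42 fell and 1 did not pass, or 43 fell adjusted over the list alone, with a median log2 fold change of -1.87. The cyclin gene Ccnb2 went from 60.7 CPM ± 5.49 to 8.37 CPM ± 0.0928 (SD, n = 2 each). Thymidine kinase (Tk1), the ubiquitin-conjugating enzyme gene Ube2c and the mitotic kinase gene Aurkb fell by 2.56, 2.31 and 2.48 on the log2 scale (SE 0.12, 0.10 and 0.12). The camera adjusted p was 6.49e-17 with the preset correlation, and the adjusted p = 0.471 with an estimated correlation. Of 48 cytosolic ribosomal protein genes, 43 fell and 5 did not pass, or 44 fell adjusted over the list alone, with a median of -0.58 (camera adjusted p of 2.18e-09, and adjusted p = 0.687 with an estimated correlation). Rpl3, Rpl10a, Rpl12 and Rpl11 fell by 1.21, 1.22, 0.91 and 0.84. Reads of ribosomal protein genes can be shared with their many processed pseudogenes, so values of single members are uncertain. Of 25 genes of cholesterol synthesis, 20 fell and 5 did not pass, or 21 fell adjusted over the list alone, with a median of -0.75. Dhcr7, Insig1, Fdps and Cyp51 fell by 1.60, 1.06, 0.92 and 0.93 (SE 0.13, 0.11, 0.10 and 0.11). This list had a camera adjusted p of 4.1e-06, and an adjusted p = 0.378 with an estimated correlation. Of 27 p53 targets and DNA damage genes, 5 rose and 8 fell, with the same counts adjusted over the list alone. Gadd45b and Plk2 rose 5.16-fold and 3.76-fold, and Sesn1 and Btg2 fell, with log2 fold changes of -3.42 and -2.06. Of eosinophil, mast cell and basophil, and platelet markers, 8 of 9, 8 of 10 and 12 of 12 were higher in the same libraries.

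Most tested genes of glycolysis and of the oxidative stress response were higher. Of 31 glycolysis and hypoxia genes, 20 rose, 4 fell and 7 did not pass, or 21 and 4 adjusted over the list alone, with a median log2 fold change of 0.71. The glucose transporter gene Slc2a1, the glycolytic regulator gene Pfkfb3, lactate dehydrogenase (Ldha) and enolase (Eno1) rose 3.2-fold, 3.53-fold, 2.52-fold and 2.31-fold. The camera adjusted p was 0.00124 with the preset correlation, and the adjusted p = 0.687 with an estimated correlation. Of 24 NRF2 and oxidative stress genes, 14 rose, 3 fell and 7 did not pass, with the same counts adjusted over the list alone and a median of 0.52. Heme oxygenase (Hmox1) rose from 1735 CPM ± 87.9 to 7703 CPM ± 287, the autophagy receptor gene Sqstm1 from 402 CPM ± 15 to 2335 CPM ± 162, and the cystine transporter gene Slc7a11 from 23.5 CPM ± 5.77 to 609 CPM ± 45.1 (SD, n = 2 each). This list had a camera adjusted p of 0.0118, 0.0645 without knockout replicate 1, and an adjusted p = 0.845 with an estimated correlation. Of 30 genes of the unfolded protein and integrated stress response, 15 rose and 11 fell, or 15 and 13 adjusted over the list alone (camera adjusted p of 0.324, fry adjusted p of 0.0104). Trib3, Atf5 and Slc3a2, which respond to amino acid shortage through the factor Atf4, rose 12.1-fold, 5.74-fold and 4.82-fold. Of 38 nuclear genes of the mitochondrial respiratory chain, 13 fell, 4 rose and 21 did not pass, with the same counts adjusted over the list alone (camera adjusted p of 0.0427, which 5 other settings ended, fry adjusted p of 0.0522, and adjusted p = 0.828 with an estimated correlation). Changes there were small, with Atp5c1, Uqcrfs1 and Ndufa4 falling by 0.50, 0.50 and 0.55, and Atp5b rising 1.37-fold. Of 15 mitochondrially encoded transcripts, 7 rose and 8 did not pass, or 8 rose adjusted over the list alone (camera adjusted p of 0.0919, but 0.0451 with the replicate block and 0.0229 without knockout replicate 1). The ribosomal RNAs mt-Rnr2 and mt-Rnr1 rose 2.91-fold and 2.26-fold, and mt-Cytb 1.74-fold. In the same libraries 12 of 12 platelet, 8 of 9 eosinophil, 8 of 10 mast cell and basophil and 6 of 9 erythroid markers were higher.

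Genes of cyclic AMP signalling moved in both directions. Of 36 components of the pathway, 14 rose, 12 fell and 10 did not pass, with the same counts adjusted over the list alone, a median of -0.01 and a mean of 0.22. The phosphodiesterase genes Pde10a, Pde4d and Pde4b, whose enzymes break down cyclic AMP, rose 6.64-fold, 5.43-fold and 2.25-fold, and the scaffold gene Akap13 rose 2.08-fold. Of 13 Gs-coupled receptor genes, 5 rose and 5 fell, or 6 and 5 adjusted over the list alone. The adenosine receptor genes Adora2a and Adora2b rose 6.9-fold and 3.51-fold, and Gpr84, a receptor for medium-chain fatty acids, rose 3.93-fold. Gpr84 is known to couple to Gi and not to Gs, so its place on that list is doubtful. Of 29 cAMP-responsive (CREB) target genes, 14 rose, 8 fell and 7 did not pass, with the same counts adjusted over the list alone and a median of 0.31. Ptgs2, the inducible cyclooxygenase, Il1rn and Maff rose 40.8-fold, 29.8-fold and 9.63-fold, and Fos fell by 3.38 (SE 0.11) on the log2 scale. None of the adenylyl cyclase, pathway component, Gs-coupled receptor and CREB target lists passed camera, with adjusted p values of 0.79, 0.995, 0.731 and 0.276, while all 4 passed fry, with adjusted p values of 0.0151, 0.0151, 0.00845 and 0.025. Their members go both ways, so such tests decide little for them.

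Markers of other marrow-derived cells were higher in the knockout libraries. Of 12 megakaryocyte and platelet markers 12 rose, with a median log2 fold change of 2.55. Itga2b and Itgb3, the platelet integrin genes, rose 7.44-fold and 7.27-fold, Vwf 8.3-fold and Nrgn 5.38-fold. Of 9 eosinophil markers 8 rose, with a median of 3.41, or 3.07 with the member that had no control count at its bound. Prg2, the gene of major basic protein, rose from 26.4 CPM ± 1.02 to 219 CPM ± 41.8 (SD, n = 2 each), and the eosinophil peroxidase gene Epx and Ccr3 rose 10.6-fold and 17.5-fold. Of 10 mast cell and basophil markers 8 rose, with a median of 3.12. The basophil protease gene Prss34 rose 13.2-fold, Gata2 7.82-fold, Tpsb2 30.4-fold and the carboxypeptidase gene Cpa3 21.4-fold. Of 9 erythroid markers 6 rose, with the globin genes Hbb-bt, Hba-a1 and Hbb-bs rising 11.9-fold, 7.34-fold and 6.52-fold, and the transferrin receptor gene Tfrc 3.39-fold. The control held at least 1 CPM of only 1 of these 9 markers, with Hbb-bt at 0.737 CPM and Hba-a1 at 0.974 CPM. Of 12 B cell markers 9 rose and 2 fell, with Cd79a and Igkc rising 11.4-fold and 6.06-fold and Blnk 3.25-fold. Of 8 tested T and NK cell markers, from a list of 18, 4 rose and 1 fell. The control held at least 1 CPM of 3 of these 8. Thy1, Lck and Il7r rose 59.7-fold, 6.7-fold and 15-fold, and Gzmb, with no count in the control, was at least 19.5-fold higher. These were the 4 that rose, so no Cd3, Cd4, Cd8 or T cell receptor gene of the list was called higher. Il7r was already at 7.89 CPM in the control. Thy1 is also on the stromal list, and Gzmb passed the count filter only through the knockout libraries. For these 6 lists the counts adjusted over the list alone were the same. Their camera adjusted p values were 1.15e-05, 0.000593, 0.000972, 0.000972, 0.00213 and 0.0105 in that order, and each list had an adjusted p = 0.217 with an estimated correlation.

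The remaining cell type lists gave weaker or mixed changes. Neutrophil markers had a median of -0.05, with 5 of 18 rising, 7 falling and 6 not passing, and the same counts adjusted over the list alone. Lcn2, an iron-binding secreted protein, rose 2.77-fold, while Ly6g, Retnlg and Csf3r fell by 1.28, 1.10 and 1.41 on the log2 scale (SE 0.15, 0.10 and 0.11). Of 17 dendritic cell markers 8 rose and 4 fell, with the same counts adjusted over the list alone. The migration genes Ccr7 and Fscn1 rose 17.1-fold and 15.4-fold, Ccl22 rose 22.7-fold and Cd24a 4.74-fold. Of 14 progenitor markers 7 rose and 2 fell, or 9 and 2 adjusted over the list alone, with Kit and Sox4 rising 7.36-fold and 7.69-fold and Spink2 falling by 2.80 (SE 0.38). This list had a camera adjusted p of 0.0241, 0.0876 without knockout replicate 2, and an adjusted p = 0.241 with an estimated correlation. Of 11 stromal and fibroblast markers 4 rose and 7 did not pass, with the same counts adjusted over the list alone. Dcn rose 127-fold and Pdgfrb 5.72-fold, and Lum, with no count in the control, was at least 13.6-fold higher. That list had a camera adjusted p of 0.0286, 0.122 without knockout replicate 1, 0.0798 without control replicate 2, a fry adjusted p of 0.201, and an adjusted p = 0.241 with an estimated correlation. Of 7 endothelial markers 4 rose and 3 did not pass, with the same counts adjusted over the list alone. Esam rose 3.81-fold, while Pecam1 and Egfl7, higher by 1.38-fold and 1.5-fold, lost their call under some settings. Of 9 osteoclast markers 5 rose and 3 fell, with the same counts adjusted over the list alone. The acid phosphatase gene Acp5 and cathepsin K (Ctsk) rose 8.46-fold and 10.1-fold, and Tnfrsf11a fell by 2.22 (SE 0.14). The dendritic cell, endothelial and osteoclast lists did not pass camera, with adjusted p values of 0.21, 0.0743 and 0.134, but passed fry, with 0.00732, 0.0104 and 0.00463. None of the 4 tested sex-linked genes passed in edgeR's test, with Eif2s3y at -0.31 (SE 0.14) and Ddx3y at 0.22 (SE 0.18) on the log2 scale, and 0 had an unadjusted p under 0.05. DESeq2 and limma-voom called 0 of them. The log2 fold change of Eif2s3y passed without knockout replicate 2 (-0.54), and the log2 fold change of Ddx3y without knockout replicate 1 (0.51).

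**Figure D3:**
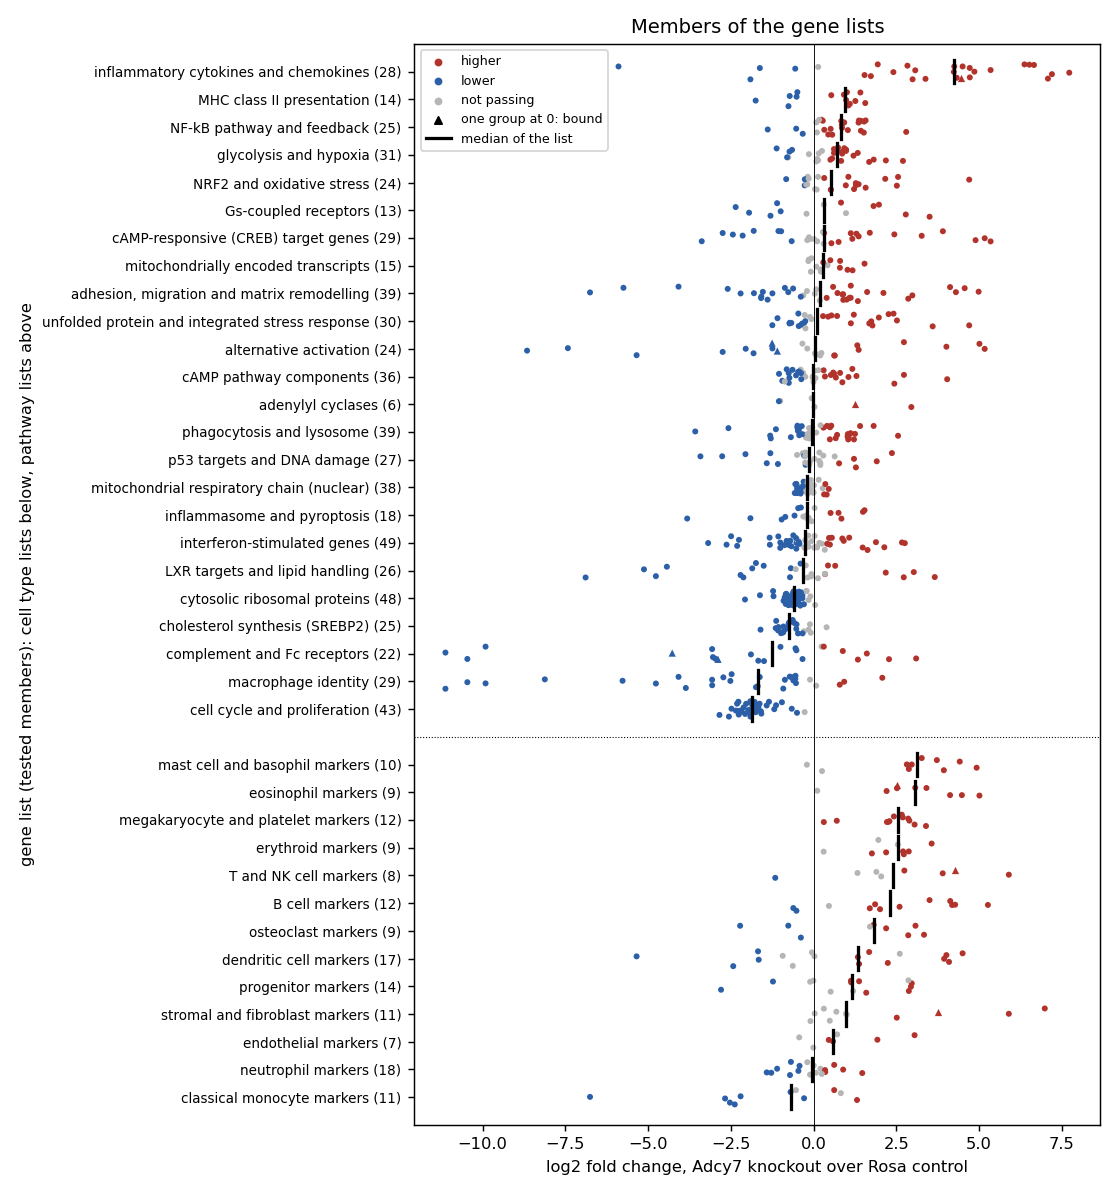
Log2 fold change (Adcy7 knockout over Rosa control) of each tested member of 24 pathway lists and 13 cell type lists, in red or blue where the gene was higher or lower at an adjusted p under 0.05, with a black line at each list's median. The median of the 28 cytokine and chemokine genes lies at 4.25 and that of the 43 cell cycle genes at -1.87.

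Genes next to the targeted sites were compared because a cut can remove or silence sequence around it. Of 8 tested genes within 500 kb of Adcy7, 2 rose and none fell in edgeR's quasi-likelihood test. No neighbour was lower at an unadjusted p under 0.05 either (0 genes), and DESeq2 and limma-voom called 0 lower. The genes that rose were Tent4b and Nod2, named after their values were seen, with log2 fold changes of 0.91 (SE 0.11) and 0.85 (SE 0.14). Of 19 tested genes within 500 kb of Gt(ROSA)26Sor, 6 rose and 5 fell. The genes that passed near both sites together, 13, were 8 without the low-count filter and 8 to 17 with 1 library left out. The share of genes that passed ranged from 18.2% of 11 tested genes on chromosome Y to 53.2% of 586 on chromosome 15. No chromosome differed from the others at an adjusted p of 0.05 (Fisher's exact test, two-sided, over the edgeR calls), and 1 did at an unadjusted p under 0.05, chromosome 13 with 44.2% (p = 0.00595, adjusted p = 0.131). With DESeq2's calls 1 chromosome passed, without the low-count filter 2, and with 1 library left out 0 to 3.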

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

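Counts divided by 4, and the other settings for neighbours and chromosomes, were chosen after the data were seen, and the rest before. The number of genes changed in Adcy7 knockout, 7848, ranged from 6167 (no low-count filter) to 7852 (RLE factors) over the settings with all 4 libraries and a threshold of 0.05, were 5652 at 0.01, and were 6091 to 7554 when 1 library was left out, where a lone library is assumed to vary like the other group. No gene that passed had the other sign under any setting with all 4 libraries, and 1 did without control replicate 1 or 2. The Adcy7 log2 fold change kept its direction and its call under every setting run, at -1.09 to -1.01 with 1 library left out. With an estimated correlation 0 pathway lists and 0 cell type lists passed in place of 10 and 9, and fry passed 17 pathway lists. The test with an estimated correlation had only 2 residual degrees of freedom, so these losses do not show that correlation ended the calls. Camera with the preset correlation no longer passed the nuclear respiratory chain list with upper-quartile factors (adjusted p 0.0556), CPM above 1 (0.0959), counts divided by 4 (0.0846), without knockout replicate 2 (0.126) and without control replicate 2 (0.104). It no longer passed NRF2 genes without knockout replicate 1 (0.0645), progenitor markers without knockout replicate 2 (0.0876), and stromal markers without knockout replicate 1 (0.122) and without control replicate 2 (0.0798). Stromal markers had too few genes for the test at CPM above 1. Mitochondrially encoded transcripts passed with the replicate block (0.0451) and without knockout replicate 1 (0.0229). Neighbours of both target sites that passed numbered 13, 8 without the filter, and 8 to 17 with 1 library left out. The chromosomes that differed numbered 0, 2 without the filter, 1 with DESeq2, and 0 to 3 with 1 library left out. The cause of these shifts was not tested. Of the named genes, Pecam1, Adcy8 and Egfl7 lost their call under some settings, Adcy8 without the filter (adjusted p 0.0763), without control replicate 1 (0.142) and without control replicate 2 (0.139), Egfl7 with DESeq2 too (adjusted p 0.12, with a range of 0.0518 to 0.199 over the settings that lost it). The replicate numbers share only a number: differences between replicates 1 and 2 correlated across genes at 0.015 between groups. With the replicate block 7843 genes passed, and of named genes none lost its call. The median of dendritic cell markers was 1.34 over 17 genes, 1.35 with RLE and 1.36 with upper-quartile factors, but -0.02 without the filter and -0.01 with DESeq2, each over 20 genes. DESeq2 changed the genes tested as well as the scaling. Depth limits genes near the floor, such as Adcy8.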

Other observations

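The genes of this paragraph and the tests on symbol families, interferon genes, CREB targets, the late TLR list, neutrophil markers, scaling, neighbours of Adcy7 and the rank of Adcy7 were chosen after the results were seen, and the test on further markers of eosinophils, mast cells and platelets was set before its values were seen. Among abundant genes outside the lists, Inhba, which codes for a subunit of activin, rose from 2.04 CPM ± 0.0481 to 772 CPM ± 201 (SD, n = 2 each), a log2 fold change of 8.57 (SE 0.21). Slc7a2, an arginine transporter gene, rose from 1.87 CPM ± 1.08 to 647 CPM ± 36.2 (SD, n = 2 each), a log2 fold change of 8.43 (SE 0.23). Serpinb2, a protease inhibitor gene, and Clec4e, a receptor for mycobacterial lipids, rose with log2 fold changes of 5.71 (SE 0.20) and 3.26 (SE 0.14). Acod1, whose enzyme makes itaconate, was at 3259 CPM in the knockout and 647 CPM in the control, and Saa3, an acute phase gene, at 21930 CPM and 5756 CPM. In the other direction, the cyclin gene Ccnd1 went from 451 CPM ± 22.4 to 8.8 CPM ± 0.097, and Selenop, which codes for a secreted selenium carrier, from 720 CPM ± 15.1 to 32 CPM ± 1.45 (SD, n = 2 each). Each of these genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Gapdh stood at 717 and 329 CPM in knockout replicates 1 and 2 and at 85.2 and 78.3 CPM in control replicates 1 and 2, a spread that may come from reads split among its copies, which was not tested.

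Gene families were formed from symbol stems with at least 10 tested members. Of 153 families, 8 passed camera with the preset correlation, and none with an estimated correlation (0, with the smallest adjusted p at 0.999). With 2 residual degrees of freedom and 153 families, that second test could hardly pass any. The variable segments of immunoglobulin heavy chains (Ighv) had 20 of 32 members higher with a median log2 fold change of 3.24, and those of kappa light chains (Igkv) 18 of 25 higher with a median of 3.01. Guanylate-binding proteins (Gbp) had 9 of 10 members higher with a median of 2.24. Of 18 Ifi genes 15 fell and 1 rose, although both groups of genes respond to interferon. The Mcm family, which holds the replicative helicase, had 8 of 10 members lower and 2 higher. Segments of 1 family share sequence, so their reads can be split among members. A segment with almost no control counts passes the count filter only through the knockout libraries, and can then only be higher. How many segments this holds for was not counted.

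Inflammatory genes were higher and macrophage identity genes lower. A stronger antiviral interferon response in the knockout cultures stays open. The median of interferon-stimulated genes was -0.24 (95% bootstrap limits over 49 genes -0.52 to 0.04), but 13 rose and 21 fell, which decides little. Of all tested genes 25% were higher. By family, 9 of 10 Gbp genes were higher, while 15 of 18 Ifi genes fell and 1 rose. Both families have members on that list, so they add little to it. Ifnb1 was higher from few counts (log2 fold change 3.1, SE 0.89). Lower cAMP signalling through loss of Adcy7 may contribute and stays open. The CREB target median of 0.31 had limits on both sides of 0 (-0.14 to 1.17 over 29 genes). Ptgs2 of that list is also on the cytokine list. Inflammation may raise such members by itself, so the median could miss lower cAMP signalling. An inflammatory stimulus such as endotoxin in the cultures or in a virus preparation may also be the source: 71.8% of a list of late TLR response genes were higher (28 of 39, with 5 lower), where 25% of all tested genes were, though part of that list had been seen before. The stimulus and the target cannot be told apart, because the labels give no number of preparations.

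Markers of other blood cell types were higher in the knockout. A lower share of macrophages with the other cells unchanged would raise neutrophil markers alike if the macrophages did not express them. Their median was -0.05 (95% bootstrap limits -0.57 to 0.30, 18 genes). That was below the median of eosinophil, mast cell and platelet markers together (2.88, limits 2.52 to 3.27, 31 genes). The control cultures held at least 10 CPM of 18 of 18 neutrophil markers. For eosinophil, mast cell and basophil, and platelet markers this was 1 of 9, 1 of 10 and 3 of 12. Whether macrophages expressed the neutrophil markers was not tested. The limits treat genes as independent, while the estimated correlation of the neutrophil list was 0.712. This explanation therefore stays open. More eosinophils, basophils or mast cells, and megakaryocytes or platelets may be present: of 21 tested genes of a further list of their markers, 76.2% were higher, but 3 (Rgs18, Nfe2 and Ltc4s) were lower, more than the 10% allowed beforehand, so this stays open. Prg2 reached 219 CPM and Itga2b 77.8 CPM, while Pf4, the platelet marker with the highest level, and Ppbp rose only from 162 to 198 CPM and from 15.2 to 24.5 CPM, and Siglecf did not pass (log2 fold change 0.11, SE 0.21). The control cultures held at least 1 CPM of 7 of 12 platelet, 4 of 9 eosinophil and 3 of 10 mast cell and basophil markers, other fixed lists hold 2 members of each, and the labels name no sort that would remove such cells.

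Adcy7 mRNA was lower but still present. Loss of a chromosome segment that takes in its tested neighbours would lower them, and 0 of 8 were lower; a shorter loss was not tested. Scaling of the libraries stays open: the log2 fold change farthest from the main value under 4 other scalings was -1.02, but these moved the median gene by 0.023 at most, too little to test a change of this size. Adcy7 may also have fallen as 1 of the many genes of the broad change and not through the guide: 11.8% of tested genes had a log2 fold change at or below that of Adcy7, 1550 of them past the threshold. Decay of edited mRNA and incomplete editing were not tested.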
